A study of Synechococcus sp. CC9902 with 12 samples.

How the data were processed

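Transcript levels were measured on 12 single-colour Agilent oligonucleotide arrays of a custom design. Each array received cDNA from 1 sample, carrying an Alexa Fluor dye. Per the labels, 6 samples came from cultures of the marine cyanobacterium Synechococcus sp. strain CC9902, harvested in exponential phase from artificial seawater medium, of which 3 had received copper as CuEDTA at 10 µM for 2 h and 3 were controls. The other 6 came from bottle incubations of natural seawater microbes in the Southern California Bight, given CuSO4 at 8 nM or nothing for 2 h. Per the labels' protocols, total RNA was extracted with Trizol, culture RNA was labelled without amplification, and field RNA was amplified with a low-input kit before labelling.

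For 2 of the 6 field samples, both of replicate number 2, the title names one treatment while the source name and treatment protocol name the other. These samples were placed in groups of their own and kept out of the field comparison, which therefore had 2 copper and 2 control samples. Both readings of the labels, with all 6 samples, were run as alternatives. Nothing in the labels says whether replicates were separate cultures or separate bottles drawn from 1 batch of water, so the p-values measure the spread between these samples, part of which may be technical.

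The authors deposited the scanner output of each array, in which the processed signal is a background-corrected intensity on a linear scale. Per the file headers, the culture arrays were read with Agilent Feature Extraction 10.7.3.1 and the field arrays with version 10.10.1.1, whereas the submitters' processing notes name 10.10.1.1 for all. A table of log2 values that the authors deposited for the same arrays was compared with the scanner signals. For 99.92% to 99.98% of probes its differences between arrays matched the log2 processed signal scaled to each array's 75th percentile within a tolerance of 0.02, and each probe in it was centred on its median over the 6 arrays of its experiment. Its column medians ran from -0.545 to 0.219 for the culture and from -0.049 to 0.111 for the field, and its scale, centring and direction are thus settled. It served as an alternative only, and 0 per-sample columns were left unused. How the probes were designed is not given in the sources used here.

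The array held 15024 probes of 5238 genes besides controls. The locus tags assign 6878 probes to 2312 genes of strain CC9902, with 3 probes for 2260 of them. Probe annotation gives a product for 2307 of these genes, of which 928 are annotated as hypothetical. A further 8103 probes belong to 2893 genes with the prefix sync_, a second genome whose strain the files do not name and whose genes they do not pair with products. The remaining probes were 23 for 13 genes with the prefix RF and 20 without a locus tag.

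Signals were taken as log2 of the processed signal minus the array's 75th percentile over non-control probes. Between 54.9% and 68.9% of all probes were well above background on each array. Spots with an outlier mark were left out, between 11 and 19 per culture array and between 298 and 553 per field array, and a probe so marked on any array of an experiment was left out of that experiment. No spot was saturated, with a count of 0 on every array. Probes of a gene were averaged on the log2 scale. A gene was tested if any of its probes was well above background on at least 3 arrays in the culture or at least 2 in the field, without regard to group. The number of arrays limits the precision.

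Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package at version 1.17.8 and plots drawn with matplotlib 3.10.9 in Python 3.11.15. P-values were adjusted by Benjamini-Hochberg, and a gene is called past an adjusted p of 0.05. The culture comparison tested CC9902 genes, the field comparison tested the genes of every genome on the array, and the difference between both copper effects was an interaction contrast over 10 arrays for CC9902 genes tested in both. Each experiment lay on 1 slide and 1 scan, so slide and scan add nothing within an experiment, while between the experiments slide, scanner software, copper salt, dose, amplification and community differ together and cannot be told apart.

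Gene lists were fixed from product text before the data were examined, for chaperones and proteases, oxidative stress and redox, copper and other metal homeostasis, iron acquisition and storage, iron-sulfur cluster assembly, photosystem II, photosystem I, phycobilisome, electron transport and cytochromes, NDH-1 complex, ATP synthase, carbon fixation and carboxysome, chlorophyll and haem synthesis, high light inducible proteins, DNA repair, sigma factors and two-component regulators, ribosomal proteins, aminoacyl-tRNA synthetases, nitrogen assimilation, phosphate acquisition, sulfur and cysteine metabolism, glycosyltransferases, ABC transporters and mobile elements. Lists with at least 5 tested members were compared with the other tested genes by camera with a preset correlation of 0.01, then with an estimated correlation. A different question, whether the members of a list move one way on balance against no change, was tested by fry. Mobile elements had 4 members and were not tested. Some names cover more than they say. The DNA repair pattern also caught 3 carboxysome genes, and the copper list holds peptidases that bind zinc and general cation efflux proteins.

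Genes are named by a rule fixed before the data were examined: the 12 largest rises and the 12 largest falls among called genes whose copper and control arrays do not overlap, the members of each list with the smallest p, and a short list of stress, photosynthesis and iron genes. Where fewer than 5 genes pass in a direction, those with the smallest p are named instead. The rule allows up to 4 members per list. The text mostly keeps to fewer, and to a pair of sync_ tags per direction, which was decided after the values were seen, as was every gene introduced here as lying outside the rule. ClpB, on the fixed short list, could not be matched to any product text.

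Same-numbered culture samples deviated together from their group means. The correlation across genes was 0.403, 0.491 and 0.384 for the 3 same-numbered pairs and between -0.474 and 0.0445 for the others. Deviations from a group mean sum to zero, so the low values of the other combinations are partly built in. The replicate numbers of the titles were taken to pair the culture samples. The main fit, which sets the calls, the named genes and the list counts, nevertheless has no block. Values from a fit with the replicate number as a block stand beside a result wherever they change a call. With 2 pairs in the field the numbers were not taken as pairs. No samples were duplicates: correlations between arrays across genes ran from 0.967 to 0.995 in the culture and from 0.949 to 0.982 in the field.

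Alternatives fixed before the data were examined covered normexp background correction with an offset of 50, quantile normalization, scaling to the median of detected probes, the filter on dim genes, the brightest probe per gene, the authors' values, a trended and robust variance, the replicate block, stricter thresholds, the genes tested, the label readings, the positive-and-significant detection mark, and leaving out each array. Scaling over CC9902 probes alone and trimmed versions of the DNA repair and chaperone lists were added after seeing the data. The pipeline was tested on simulated data drawn with the spread of the real genes, each gene independent of the others. Changed genes were picked at random and shifted alike on every copper array. With 200 of the 2309 culture genes changed, 93.4% of 2-fold and 99.8% of 4-fold changes were called, and 3.57% of calls were false. With 200 of the 4651 field genes changed, the shares were 43.6%, 99.8% and 6.45%. Simulated lists of 20 shifted genes had an unadjusted camera p under 0.05 in 5 of 5 runs in either design, and unchanged lists in 0. With genes drawn independently, these runs cannot test the preset correlation.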

Results

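The data consist of 12 arrays. In the culture experiment 3 arrays carried RNA from strain CC9902 after 2 h with 10 µM copper and 3 carried RNA from untreated cultures. In the field experiment 2 arrays carried RNA from bottles with 8 nM copper, 2 from control bottles, and 2 from bottles whose labels contradict each other on the treatment. Strain CC9902 is a marine picocyanobacterium, and copper is an essential metal that becomes toxic to such cells at higher levels. The 75th percentile of the probe signal, the measure of brightness on these arrays, ran from 1650 to 4750 intensity units in the culture, highest in control replicate 2, and from 132 to 201 in the field. On the culture arrays 98.9% to 99.5% of CC9902 probes were well above background, and on the field arrays 69.0% to 83.9%.

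The culture comparison asked how the transcripts of CC9902 differ after 2 h with copper. Copper-treated cells held far more mRNA for 7 of 28 chaperones and proteases, and less for 3 of the 4 genes annotated as porins, 2 of 9 iron genes and the light-harvesting protein PcbD. The transcript of a putative small heat shock protein (Syncc9902_2178) rose 13.9-fold, and that of heat shock protein 90 (Syncc9902_1082), a chaperone that assists late folding steps, rose 11.5-fold. A possible porin (Syncc9902_1999), a channel of the outer membrane, fell 17.8-fold, and the chlorophyll a/b binding light harvesting protein PcbD (Syncc9902_1005) fell 14.2-fold. Of 2309 genes tested, 41 were called, 24 higher and 17 lower with copper, and 16 of the 41 are annotated as hypothetical.

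All 41 called genes had copper and control arrays that did not overlap and every probe moving the same way, and 37 changed at least 2-fold, 22 higher and 15 lower. At an unadjusted p under 0.05 there were 310 genes, where 115.4 would be expected by chance. Copper and control arrays did not overlap for 458 of the 2309 genes, or 19.8%, against 10% by chance. Of the calls, 58.5% were higher, and after quantile normalization 44.1% were, with 15 of 34 called genes higher, of which 32 genes were shared with the 41. With the replicate number as a block 82 genes were called, 56 higher and 26 lower, and 40 of the 41 stayed called, the exception being a short chain dehydrogenase (Syncc9902_1632), whose adjusted p moved from 0.0497 to 0.0516. The rises depended on single arrays more than the falls did: 3 genes were called higher and 7 lower without copper replicate 1, 0 and 8 without control replicate 1, 1 and 11 without copper replicate 2, 53 and 38 without control replicate 2, 57 and 23 without copper replicate 3, and 3 and 10 without control replicate 3. Of the 13 called rises named by the rule, 3, 0, 1, 13, 13 and 3 stayed called in these fits, in the order given, and of the 13 falls 7, 8, 9, 13, 12 and 9. The fits without single arrays did not use the replicate block, so variation shared within pairs stayed in their spread. With the genes of every genome tested, 0 of the 13 rises and 2 of the 13 falls stayed called.

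**Figure D1:**
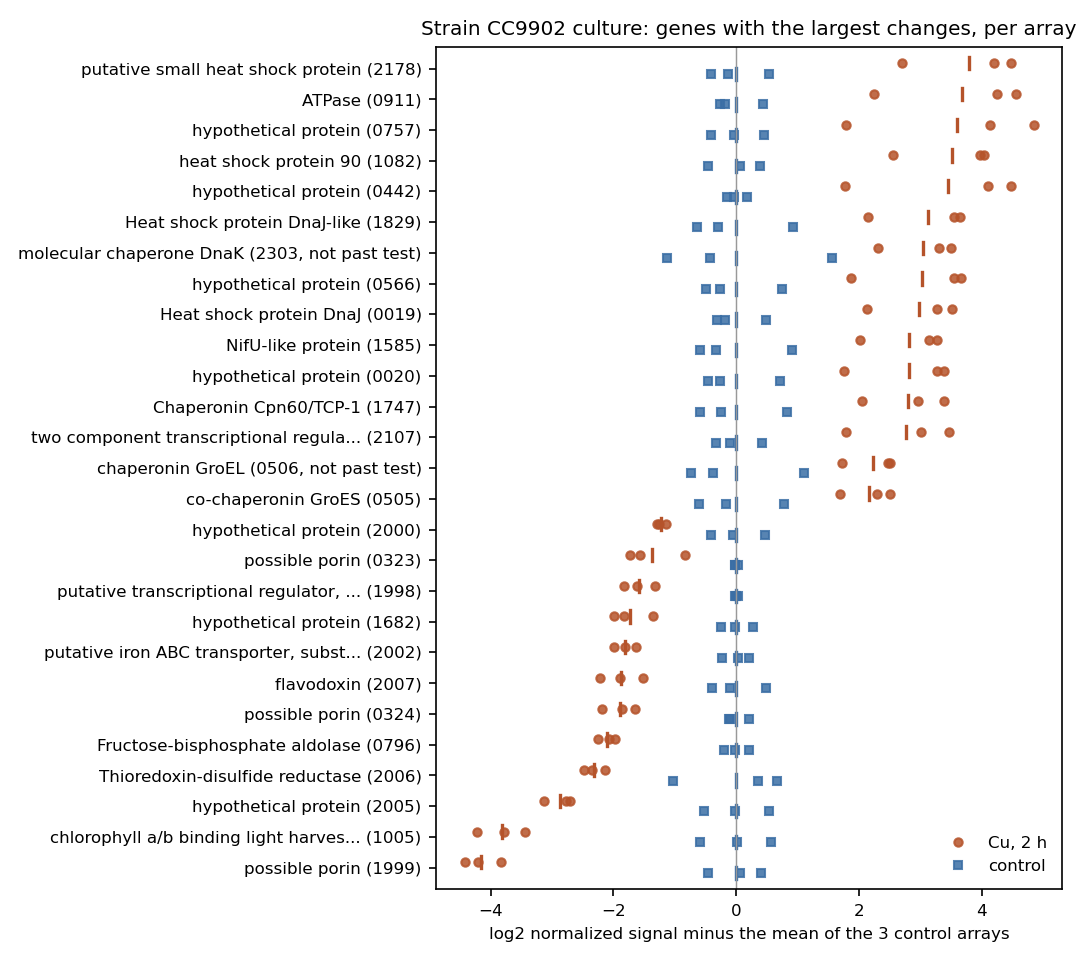
Each row is a CC9902 gene, by product and number of its locus tag, and the horizontal axis gives the log2 normalized signal minus the mean of the 3 control arrays; circles are the 3 copper arrays, squares the 3 control arrays, and short vertical bars the group means. The 12 largest rises and 12 largest falls among called genes are drawn with GroES and the uncalled DnaK and GroEL, and their mean changes run from -4.16 for a porin to 3.80 for a small heat shock protein.

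Among the 28 chaperone and protease genes, 7 rose, 1 fell and 20 did not pass the test. Adjusted over the list alone, 9 rose and 1 fell. The log2 signal of the small heat shock protein (Syncc9902_2178) was 6.85 ± 0.96 (SD, n = 3) with copper and 3.06 ± 0.49 (n = 3) in the controls, a log2 change of 3.80 ± 0.46 (SE, adjusted p = 0.00740). Heat shock protein 90 (Syncc9902_1082) changed by 3.52 ± 0.40 (adjusted p = 0.00673) and DnaJ (Syncc9902_0019), a co-chaperone of DnaK, by 2.98 ± 0.37 (adjusted p = 0.00868). A DnaJ-like protein (Syncc9902_1829) rose by 3.12 ± 0.50, the chaperonin Cpn60 (Syncc9902_1747) by 2.81 ± 0.43, the co-chaperonin GroES (Syncc9902_0505) by 2.17 ± 0.36 and, outside the naming rule, an FtsH membrane protease (Syncc9902_1483) by 2.29 ± 0.40. Also outside that rule, the FtsH genes Syncc9902_1061, Syncc9902_1152 and Syncc9902_2043 were not called, at 0.33, 0.24 and 0.30. Nor were the DnaJ-like genes Syncc9902_0326, Syncc9902_0618, Syncc9902_0976 and Syncc9902_1093, at 0.0008, 0.26, -0.26 and 0.01. The call of GroES ended without copper replicate 1 or 2 or control replicate 1 or 3, and with normexp background correction (2.18, adjusted p = 0.0531) and quantile normalization (1.99, adjusted p = 0.069). Chaperonin GroEL (Syncc9902_0506) stood at 2.23 ± 0.45 (adjusted p = 0.0585) and DnaK (Syncc9902_2303) at 3.04 ± 0.64 (adjusted p = 0.0667), neither past the test, whereas with replicate as a block both passed, at adjusted p = 0.0138 and 0.0188. Without control replicate 2, DnaK (Syncc9902_2303) stood at 3.82 and was called (adjusted p = 0.00346). The other DnaK genes, Syncc9902_1092 and Syncc9902_0517, had log2 changes of -0.06 ± 0.13 and -0.03 ± 0.12, with a sign that turned under other settings. GrpE (Syncc9902_0018), the nucleotide exchange factor of DnaK, was the list member that fell, by 1.1 ± 0.16 on the log2 scale (adjusted p = 0.0209), a call that ended without copper replicate 1 or 2 or control replicate 1 or 3.

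As a group the chaperone genes stood above the other genes by camera (adjusted p = 2.91e-05). That call is lost when the correlation between members is estimated (adjusted p = 0.917 with an estimated correlation), and fry, which tests the members against no change and not against other genes, gave an adjusted p of 0.243. The median member changed by 0.23 and the mean by 0.97, since most members lay near zero and a few rose strongly. In all 24 called-higher genes copper replicate 3 lay below both other copper arrays, and in 22 of the 24 control replicate 2 lay above both other controls, with a median of 0.70 log2 units above their mean. Within same-numbered pairs the change was smallest in pair 3 for 18 of the 24 and in pair 2 for 6. The number of chaperone genes called higher depended on single arrays, with 9 when copper replicate 3 or control replicate 2 was left out, 3 without copper replicate 1 or control replicate 3, 1 without copper replicate 2 and 0 without control replicate 1.

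Further rises outside the chaperone list, which was set by product text, were in genes of varied or unstated function. A product text as short as ATPase (Syncc9902_0911) leaves the role of that gene open. An ATPase (Syncc9902_0911) rose by 3.69 ± 0.55 (adjusted p = 0.0226), a NifU-like protein (Syncc9902_1585), of a family that scaffolds iron-sulfur clusters, by 2.81 ± 0.45 (adjusted p = 0.0255), and a LuxR-type two-component regulator (Syncc9902_2107) by 2.76 ± 0.41 (adjusted p = 0.0210). These 3 calls ended without copper replicate 1 or 2 or control replicate 1 or 3. Hypothetical proteins Syncc9902_0757, Syncc9902_0442, Syncc9902_0566 and Syncc9902_0020 rose by 3.59, 3.45, 3.03 and 2.81. The calls of Syncc9902_0566 and Syncc9902_0020 also ended without any 1 of these arrays. Without copper replicate 3 the rises of Syncc9902_0757, Syncc9902_0442 and the ATPase Syncc9902_0911 were 4.50, 4.29 and 4.41, and without copper replicate 2 that of Syncc9902_0757 was 2.97. The call of Syncc9902_0757 (adjusted p = 0.0497) ended in each fit without copper replicate 1 or 2 or control replicate 1 or 3, and also with normexp, quantile normalization, no filter on dim genes, the trended and robust variance and scaling over CC9902 probes, at adjusted p-values from 0.0502 to 0.0888. That of Syncc9902_0442 (adjusted p = 0.0356) ended without the same single arrays and with normexp, quantile normalization and the trended and robust variance, at 0.0519 to 0.0531. The LuxR-type gene was the 1 member of 21 sigma factors and two-component regulators that rose, and the list as a whole was not called (camera adjusted p = 0.844), with 1 member higher and 1 lower under the replicate block. In the same list an RNA polymerase sigma factor (Syncc9902_1678) stood at -0.71 ± 0.25 (adjusted p = 0.282).

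Of the 17 called falls, several lay in a run of adjacent locus tags and others elsewhere. The porin Syncc9902_1999 went from 6.53 ± 0.43 (SD, n = 3) to 2.37 ± 0.30 (n = 3), a log2 change of -4.16 ± 0.24 (adjusted p = 0.000356). In the same run of tags, the Crp/Fnr family regulator Syncc9902_1998 changed by -1.59 ± 0.15, the substrate-binding protein of an iron ABC transporter (Syncc9902_2002) by -1.81 ± 0.16, a thioredoxin-disulfide reductase (Syncc9902_2006) by -2.32 ± 0.40, and flavodoxin (Syncc9902_2007), which replaces ferredoxin in iron-poor cells, by -1.88 ± 0.26. Hypothetical proteins Syncc9902_2000 and Syncc9902_2005 in this run fell by 1.23 and 2.88. With normexp background correction the changes of Syncc9902_1998 and Syncc9902_2006 shrank to -0.64 and -0.94 and were no longer called (adjusted p = 0.325 and 0.375), and that of Syncc9902_2005 shrank to -1.82 and stayed called, while Syncc9902_2000 stood at -1.21 (adjusted p = 0.0501). The call of Syncc9902_2006 also ended with the brightest probe and without copper replicate 1, control replicate 1, copper replicate 2 or control replicate 3. With the brightest probe Syncc9902_1999 changed by -3.39 and Syncc9902_2005 by -3.49, both called. Outside the naming rule, its members Syncc9902_2001, ferritin Syncc9902_2003 and Syncc9902_2004 were not called, with log2 changes of -0.58, -0.03 and -0.46. Elsewhere the porins Syncc9902_0324 and Syncc9902_0323 fell by 1.90 ± 0.17 and 1.38 ± 0.23, while the porin Syncc9902_2012, outside the naming rule, was not called, at -0.05 ± 0.27; there were also falls of 3.82 ± 0.31 in PcbD (Syncc9902_1005, adjusted p = 0.00142), 1.72 ± 0.21 in the hypothetical protein Syncc9902_1682, and 2.10 ± 0.15 in fructose-bisphosphate aldolase (Syncc9902_0796), an enzyme of sugar metabolism and carbon fixation (adjusted p = 0.000969). Syncc9902_1999 and Syncc9902_0796 were past the threshold in every setting run. Without single arrays the call of Syncc9902_0323 ended without copper replicate 1, control replicate 1 or control replicate 3, that of Syncc9902_1682 without copper replicate 1 or control replicate 1, and that of Syncc9902_2000 without copper replicate 1, 2 or 3 or control replicate 1.

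Of the 9 iron acquisition and storage genes, 2 fell, the transporter protein Syncc9902_2002 and flavodoxin, and 7 did not pass, including ferritin. The count was 1 without copper replicate 1, copper replicate 2 or control replicate 3, where the call of flavodoxin (Syncc9902_2007) ended. Adjusted over the list alone the same count of 2 fell, and the list was not called (camera adjusted p = 0.211). None of the 5 genes on the iron-sulfur cluster list, which also holds a glycolate oxidase subunit and an Fe-S oxidoreductase but not the called NifU-like protein (Syncc9902_1585), passed over all genes tested, and 2 rose when adjusted over the list alone, SufB (Syncc9902_0404) at 0.68 ± 0.16 and SufC (Syncc9902_0405) at 0.81 ± 0.26. With replicate as a block 1 of these genes was called over all genes tested. Among 26 oxidative stress and redox genes 1 fell, the thioredoxin-disulfide reductase Syncc9902_2006, whose call depended on the setting as given above. Adjusted over the list alone 1 fell and 1 rose, a thioredoxin reductase (Syncc9902_0680) not called over all genes, at 1.19 ± 0.27 (adjusted p = 0.0822). A nickel superoxide dismutase (Syncc9902_1525) had a log2 change of -0.12 ± 0.11 and a second superoxide dismutase (Syncc9902_0982) one of 0.18 ± 0.17, neither past the test. In the list for copper and other metals 0 of 6 members passed in limma and 1 had an unadjusted p under 0.05, a zinc metallopeptidase (Syncc9902_0754) at 0.46 ± 0.18. Its members whose product names copper, added here outside the naming rule, were a copper-translocating P-type ATPase (Syncc9902_0311) at 0.06 ± 0.17 and a multicopper oxidase-like protein (Syncc9902_1384) at -0.06 ± 0.15.

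Photosynthesis lists held few calls. The 1 called member of the 19 chlorophyll and haem synthesis genes was PcbD, an antenna protein and not a synthesis enzyme. By limma 0 of 22 photosystem II genes were called, and 0 had an unadjusted p under 0.05. The psbA genes Syncc9902_1814 and Syncc9902_0943, for the D1 protein, stood at 0.35 ± 0.37 and 0.30 ± 0.38, and both lay below zero without control replicate 2, at -0.04 and -0.09. In photosystem I 0 of 14 were called and 2 had an unadjusted p under 0.05, the larger in subunit IV (Syncc9902_1441) at -1.23 ± 0.30 (adjusted p = 0.114), which was -0.48 with normexp and -0.12 with the brightest probe. In the phycobilisome list 0 of 21 were called and 1 had an unadjusted p under 0.05, a rod-core linker (Syncc9902_1003) at -1.1 ± 0.28 (adjusted p = 0.132), which was -0.34 with normexp. Both Syncc9902_1441 and Syncc9902_1003 were dim, with mean log2 signals of -5.25 and -5.50 with copper and -4.02 and -4.41 in the controls. With replicate as a block the photosystem I and phycobilisome lists each had 1 member called lower. For electron transport 0 of 42 were called, 4 having an unadjusted p under 0.05, 2 higher and 2 lower, and a ferredoxin (Syncc9902_1008) stood at -0.61 ± 0.20. Plastocyanin (Syncc9902_0916), a copper protein of photosynthetic electron transport, stood at 0.18 ± 0.22, and at -0.01 without control replicate 2. In the NDH-1 complex 0 of 17 were called and 2 had an unadjusted p under 0.05. Neither ATP synthase, with 9 genes, nor carbon fixation and carboxysome, with 12, had a call or a member at an unadjusted p under 0.05, and the large subunit of ribulose-bisphosphate carboxylase (Syncc9902_1613) stood at -0.12 ± 0.15. Of 8 high light inducible genes 0 were called and 2 had an unadjusted p under 0.05, Syncc9902_0050 at 0.54 ± 0.18 and Syncc9902_1000 at 0.51 ± 0.19, and the list, with a camera adjusted p of 0.211, was called when control replicate 2 was left out (adjusted p = 0.000664).

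The 56 ribosomal protein genes shifted upward as a group by camera (adjusted p = 0.0191), with 49 above zero and a median log2 change of 0.15, while 0 of the members were called by limma, 1 with replicate as a block, and 2 had an unadjusted p under 0.05. The call is lost with an estimated correlation (adjusted p = 0.917 with an estimated correlation) and after quantile normalization (adjusted p = 0.0823). Against no change, fry gave an adjusted p of 0.579. It also depended on single arrays, with an adjusted p of 0.164 without copper replicate 1, 0.127 without control replicate 1, 0.200 without control replicate 2 and 0.111 without copper replicate 3. The largest member value was ribosomal protein L28 (Syncc9902_1081) at 1.18 ± 0.32 (adjusted p = 0.166).

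In the remaining lists hardly a gene was called. DNA repair had 0 of 12 called by limma, 4 at an unadjusted p under 0.05, and 3 higher when adjusted over the list alone, among them RecN (Syncc9902_2318) at 1.20 ± 0.33 and a photolyase family protein (Syncc9902_1117) at 0.47 ± 0.14. With replicate as a block 1 of its members was called higher. Recombinase A (Syncc9902_1949), whose product text that list does not match, stood at -0.15 ± 0.16. Of 28 ABC transporter genes 1 fell, the iron transporter protein Syncc9902_2002, and 3 others were higher at an unadjusted p under 0.05, led by a membrane component (Syncc9902_0406) at 0.84 ± 0.24. Under the replicate block 1 of its members rose. Adjusted over the list alone 1 gene was higher in each of the aminoacyl-tRNA synthetases (22 tested, tyrosyl-tRNA synthetase Syncc9902_0567 at 0.80 ± 0.17), the glycosyltransferases (25 tested, Syncc9902_0265 at 1.34 ± 0.29) and the phosphate acquisition genes (7 tested, a possible phosphate-binding protein, Syncc9902_1707, at 1.21 ± 0.30, or 0.13 with the brightest probe), and over all genes 0 were called by limma, each list having 1 member at an unadjusted p under 0.05. The replicate block added 1 rise among the glycosyltransferases. Nitrogen assimilation had 0 of 13 called and 2 lower at an unadjusted p under 0.05, a nitrate transporter (Syncc9902_2271) at -0.64 ± 0.26 and a nitrite transporter (Syncc9902_2285) at -0.50 ± 0.16, and with replicate as a block 1 member fell. Sulfur and cysteine metabolism had 0 of 10 called and 0 at an unadjusted p under 0.05. Apart from chaperones and ribosomal proteins, camera gave adjusted p-values from 0.211 to 0.852 for the lists. Median, mean and camera direction differed in sign for electron transport (0.03, -0.002, lower), photosystem I (0.02, -0.09, lower), NDH-1 (-0.02, 0.04, higher), glycosyltransferases (-0.03, 0.03, lower) and aminoacyl-tRNA synthetases (-0.01, 0.01, lower).

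Signal on probes of the other genome can come from cross-hybridisation of CC9902 RNA, in the field also from other community members, and these sources were not separated there. Field signal on CC9902 probes can likewise come from other community members, so it cannot be credited to strain CC9902 alone. On the culture arrays 25.9% ± 1.57 (SD, n = 3) of sync_ probes were well above background with copper and 24.0% ± 2.05 (n = 3) in the controls, a difference of 1.87 percentage points (exact two-sided permutation p = 0.300, smallest possible 0.1). Their median signal was 4.25 to 5.90 units, against 1840 to 5400 for CC9902 probes. In the field bottles 55.5% ± 0.806 (SD, n = 2) of sync_ probes were well above background with copper and 44.6% ± 2.50 (n = 2) in the controls, a difference of 10.9 points (exact two-sided permutation p = 0.333, the smallest that 2 against 2 arrays allow). For CC9902 probes the field values were 81.4% ± 3.62 and 73.4% ± 6.19. The field sample with a copper title and a control source name had 56.8% of sync_ probes above background, and the one with a control title and a copper source name 41.8%. Read by title, every copper array had a larger share of sync_ and of CC9902 probes above background than every control array. Read by source name, the groups overlapped. This ordering was seen afterwards, was not tested and does not settle the labels.

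**Figure D2:**
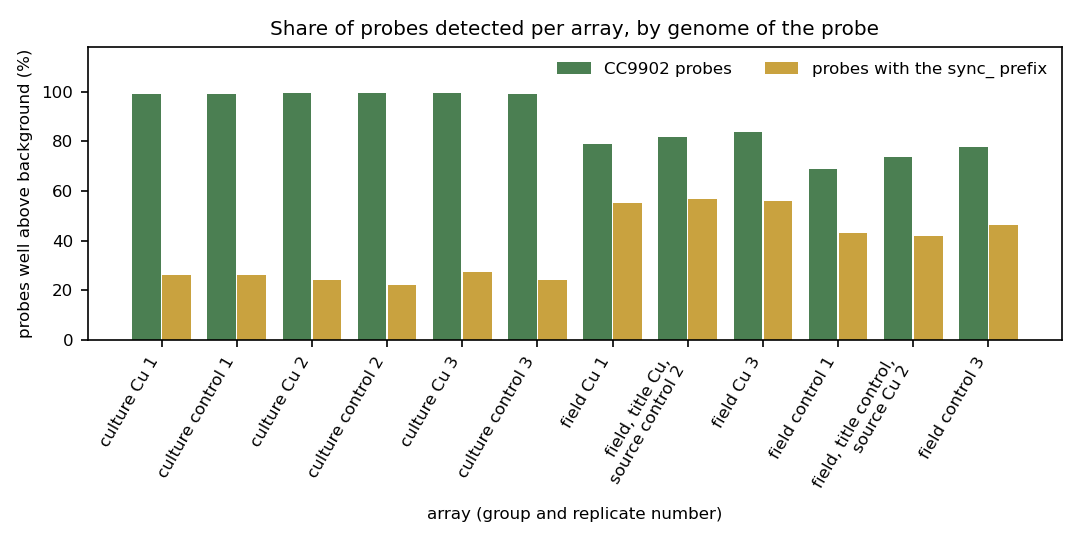
Bars give the percentage of probes well above background on each of the 12 arrays, with CC9902 probes in green and sync_ probes in yellow, and the arrays named by group and replicate number. CC9902 probes are at 98.9% or more on the culture arrays and between 69.0% and 83.9% on the field arrays; sync_ probes are between 22.0% and 27.4% in the culture and between 41.8% and 56.8% in the field.

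The field comparison asked whether 8 nM copper for 2 h moves transcripts in a natural community. None of the genes tested passed: limma called 0 of 4651 genes, of which 2232 belong to CC9902 and 2390 carry the sync_ prefix. The folding genes that rose in culture were not called here. Heat shock protein 90 (Syncc9902_1082) stood at 0.38 ± 0.29 (SE), Cpn60 (Syncc9902_1747) at 0.09 ± 0.29 and GroES (Syncc9902_0505) at 0.31 ± 0.29. With standard errors of this size a small rise is neither shown nor excluded. Values for DnaK (Syncc9902_2303) and GroEL (Syncc9902_0506) were 0.55 ± 0.30 and 0.34 ± 0.29, those for the other DnaK genes (Syncc9902_0517, Syncc9902_1092) 0.18 ± 0.28 and -0.11 ± 0.29. The iron transporter protein (Syncc9902_2002) stood at -0.02 ± 0.30.

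At an unadjusted p under 0.05 there were 90 field genes, where 232.6 would be expected by chance, and the smallest adjusted p was 1. Taking the treatment from the titles or from the source names for all 6 samples also gave 0 calls by limma, with 151 and 101 genes at an unadjusted p under 0.05. Leaving out single arrays, which leaves 1 array in an arm and assumes that it varies like the other arm, gave 12 calls without copper replicate 1, 25 without copper replicate 3, and 3 without either control array. The largest unadjusted evidence for a higher level was in sync_0606 at 1.05 ± 0.29 and sync_1689 at 1.30 ± 0.37, and for a lower level in sync_2483 at -0.94 ± 0.29 and sync_2264 at -0.97 ± 0.31, none past the threshold, and neither was the hypothetical CC9902 gene Syncc9902_1376 at -0.88 ± 0.30. Plastocyanin (Syncc9902_0916) stood at -0.05 ± 0.32, the psbA genes (Syncc9902_0943, Syncc9902_1814) at 0.37 ± 0.32 and 0.33 ± 0.31, ribulose-bisphosphate carboxylase (Syncc9902_1613) at -0.24 ± 0.41, recombinase A (Syncc9902_1949) at -0.16 ± 0.31, the superoxide dismutases (Syncc9902_1525, Syncc9902_0982) at 0.05 ± 0.29 and -0.04 ± 0.30, and high light inducible genes (Syncc9902_0824, Syncc9902_0368) at -0.14 ± 0.28 and -0.15 ± 0.32.

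By camera, against other genes, 0 of the 23 gene lists were called in the field and 0 had an unadjusted p under 0.05, among them the chaperones (28 tested, median 0.09), the iron genes (8 tested, median -0.09) and the ribosomal proteins (56 tested, median 0.04). By fry, against no change, 0 had an unadjusted p under 0.05 as well. Camera adjusted p-values ran from 0.897 to 0.995. No member of any list was called, over all genes or adjusted over the list alone, where the count was 0 for each, and 1 electron transport gene of 41 was higher at an unadjusted p under 0.05. Median, mean and camera direction differed in sign for photosystem II (-0.09, 0.03, higher), ATP synthase (-0.03, 0.05, higher), electron transport (-0.02, 0.02, lower), nitrogen assimilation (0.06, -0.07, lower) and phosphate acquisition (-0.01, 0.01, higher). With treatment taken from the source names for all 6 samples, carbon fixation and carboxysome genes were called lower (adjusted p = 0.0323).

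Whether the copper effect on the probes of a CC9902 gene differed between field and culture was tested over 2230 genes, and 1 was called. In the field these probes may also carry signal from other community members. The porin Syncc9902_1999 changed by -4.16 ± 0.24 in culture and stood at 0.39 ± 0.33 in the field, a difference, field minus culture, of 4.55 ± 0.41 (adjusted p = 0.000553). For the folding genes the differences were smaller and had larger standard errors, with -3.14 ± 0.57 for heat shock protein 90 (Syncc9902_1082, adjusted p = 0.0937) and -3.60 ± 0.71 for the small heat shock protein (Syncc9902_2178, adjusted p = 0.111), neither past the test. With replicate as a block both were past it, at adjusted p = 0.00352 and 0.0157, as were DnaJ (Syncc9902_0019, -2.84, adjusted p = 0.0118), Cpn60 (Syncc9902_1747, -2.72, adjusted p = 0.0171) and GroES (Syncc9902_0505, -1.85, adjusted p = 0.0312). In that fit, which also takes the field numbers as pairs, 17 of the 24 genes called higher in culture were lower in field minus culture and 8 of 14 genes called lower in culture were higher, so whether a difference is called for these genes depends on the block. These genes were chosen by their change on the same culture arrays, and that choice alone pushes field minus culture the other way. The counts therefore do not measure a weaker field effect. PcbD (Syncc9902_1005) stood at -1.0 ± 0.58 in the field. At an unadjusted p under 0.05 there were 158 genes, where 111.5 would be expected. The count of differing genes was 31, 10 higher and 21 lower in field minus culture, with replicate as a block, 24 and 26 with all 6 field samples by title and by source name, 35 without culture copper replicate 3, 8 without culture control replicate 2, and 2 without field copper replicate 3 or field control replicate 3. Dose, copper salt, amplification and community differ along with the experiment.

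**Figure D3:**
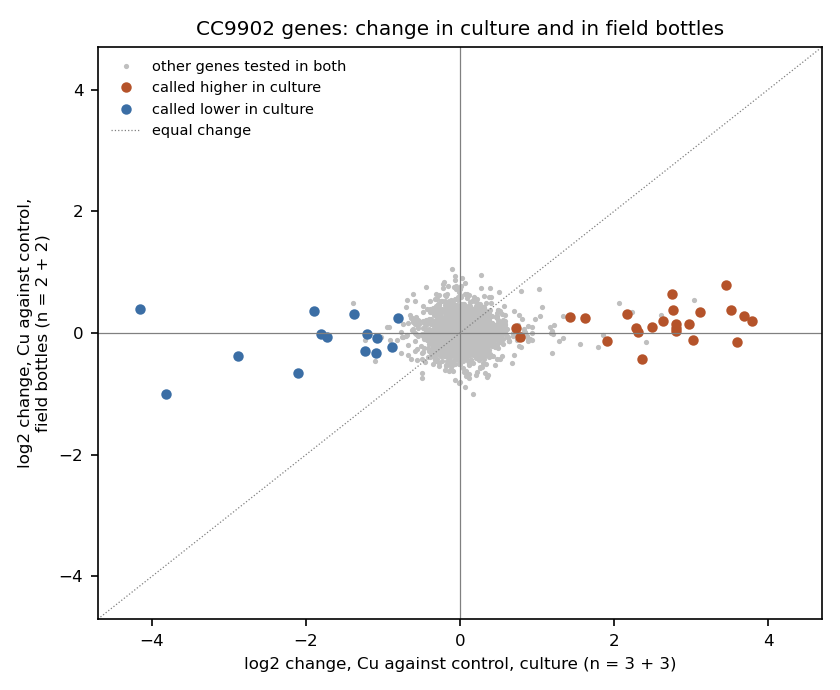
Each point is 1 of the 2230 CC9902 genes tested in both experiments, with its log2 change in culture (3 against 3 arrays) on the horizontal axis and in field bottles (2 against 2 arrays) on the vertical axis; orange and blue points were called higher and lower in culture, and the dotted line marks equal change. Genes called in culture spread from -4.16 to 3.80 horizontally, while the field changes of the same genes stay between -1.0 and 0.78. The coloured genes were chosen by their culture change, so part of the wider horizontal spread is built in.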

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

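Of the tests in this part, those of copper replicate 3, the GrpE probes, the splits of the field arrays and the culture genes in the field were chosen only after the result was seen; the fits under both label readings, the splits of the culture arrays and the simulation of array number were planned, but weighing the label readings as a cause of the missing field calls was decided after their counts were seen.

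The porin Syncc9902_1999 was singled out because its copper effect differed between the experiments: the field change exceeded the culture change by 4.55 ± 0.41 log2 units in the interaction test, and it was the 1 gene of 2230 past that test with the arrays of agreed label, where the fit with replicate as a block gave 31. Its culture change kept its direction and stayed past the threshold in every setting, from -4.38 to -3.39. Experiment, copper salt, dose, RNA amplification, slide and community change together, so the source of the difference was not tested.

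The culture count was compared with other splits of the same 6 arrays. The real split gave 41 called genes, the highest of the others gave 0, and 1 of the 10 splits, the real one, gave a count that large, while 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split had 310 genes. The 3 other splits that also part every same-numbered pair had at most 68, and the 6 that keep some pair together had up to 296.

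The first pattern is the smaller rise in copper replicate 3: in 52 genes called higher by at least 2-fold without that array, its change from the mean of the 3 controls was a median of 0.424 times that of copper replicates 1 and 2 (interquartile range 0.22), but within same-numbered pairs the median was 0.57 (interquartile range 0.344). These genes were chosen by their rise in copper replicates 1 and 2, and that choice alone lowers the ratio. In the folding genes the pattern largely depends on the baseline, since for the 7 called chaperones and proteases the ratio within pairs was 0.849 (0.662 to 1.09) and pair 2 had the smallest change in 4 of them, and for the uncalled GroEL (Syncc9902_0506) and DnaK (Syncc9902_2303) it was 1.15 and 1.22. Control RNA mixed into the sample would need a share of 73.7%, or 62.4% within pairs, shares that the choice of genes may make too high. By either baseline 14 of 18 genes called lower by at least 2-fold lay below the level such a share alone gives by more than 1 control SD. With the 5 called genes under 2-fold added, 16 of 23 lay below it against the mean of the controls. This argues against mixing at these shares, and a smaller share was not tested. A compressed signal range on that array would shrink the falls as much, and it stays open: the ratio in the 18 lower genes was 0.869 (interquartile range 0.254), or 0.873 within pairs (interquartile range 0.31), and within pairs the distance from the higher genes is less than their interquartile range. A different response of that culture may contribute and was not tested.

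The second pattern is GrpE (Syncc9902_0018), which fell beside DnaJ (Syncc9902_0019), the adjacent locus tag, which rose. One aberrant probe does not account for it: 3 of 3 GrpE probes had all copper arrays below all control arrays, with log2 changes of -1.06, -1.17 and -1.06. Over all settings the change ran from -1.23 to -0.97 and kept its direction, but the call ended without copper replicate 1 or 2 or control replicate 1 or 3, and with the genes of every genome tested. Why neighbouring genes of the same folding machine moved apart was not tested, and the product name rests on the array's annotation alone.

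The third pattern is the absence of called genes in the field bottles. Array number alone is argued against only for a response like the simulated one. There 200 genes were changed, some by 2-fold and some by 4-fold, picked at random and shifted alike on every copper array. A share of 0.998 of those at 4-fold was called in 2 against 2 arrays. Genes that respond unevenly stay open. In the culture GroEL (Syncc9902_0506) and DnaK (Syncc9902_2303) stood at 4.7-fold and 8.2-fold and were not called in 3 against 3 arrays without the replicate block. The median SD over copper arrays was 0.83 in the 24 called-higher culture genes. A response of few genes faces a stricter adjusted threshold and was not simulated, so it stays open. For 2-fold changes 43.6% were called, so smaller changes stay open too, and the simulation drew genes independently. The contradictory labels of 2 samples, taken both by title or both by source name, do not account for it, as both readings gave 0 called genes by limma, with 151 and 101 at an unadjusted p under 0.05. With a real count of 0 the number of splits that reach it says nothing, and 10 splits are too few for a share under 0.05; the highest other split of the 6 field arrays gave 8 genes, with 989 at an unadjusted p under 0.05. That split follows the replicate number in part, setting both replicate 1 arrays of agreed label against both replicate 3 arrays, while the replicate 2 arrays lie on opposite sides. It points to a structure of the samples, and the fit with replicate as a block also called 0 genes.

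Genes called higher in culture had a median field change of 0.15, with 19 of 24 above zero, and fry, limma's rotation test for a common direction, gave a p of 0.137, whereas camera, which compares them with other genes, gave a p of 0.00707. Genes called lower had a median of -0.07 over 14 genes and a fry p of 0.440. With all 6 samples the genes called higher kept a rise under both readings, with fry p-values of 0.237 by title and 0.317 by source name and camera p-values of 0.0426 and 0.0219. For the genes called lower the readings parted: by title the median was -0.16 (fry p of 0.116, camera p of 0.011), by source name it was 0.02 with 9 of 14 above zero (fry p of 0.885, camera p of 0.541). A small field response of the culture genes in the same direction may exist or not, and these tests leave it open.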

How the results depend on the processing

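Scaling over CC9902 probes alone and the trimmed gene lists were chosen only after the data were seen. In the culture, other scalings, filters, probe rules, variance models and the authors' values gave 30 to 43 called genes, and the 26 named genes that were called kept their direction in every setting. Over the named culture genes 1130 of the alternative values stayed on the same side of the threshold, 103 fell short of it, 34 newly passed it and 8 changed sign. Counts moved to 12 at an adjusted p under 0.01, 82 with the replicate block and 2 with the genes of every genome tested, where adjusting over 3897 genes and a shared variance with dim probes are part of the change. Leaving out single arrays gave 8 to 91: 10 without copper 1, 8 without control 1, 12 without copper 2, 91 without control 2, 80 without copper 3 and 13 without control 3. Fewer arrays leave less power to call genes, but the count rose without control 2 and without copper 3. Of the 24 called-higher genes, control 2 lay above both other controls in 22 and copper 3 below both other copper arrays in 24. Leaving out either array thus widens the difference in those genes. For the added falls the cause was not tested. Of the 2 called lists, 0 remained with an estimated correlation and 1, the chaperones, after quantile normalization; by fry, which tests against no change, 0 lists were called and 3 had an unadjusted p under 0.05, chaperones, iron and DNA repair. Without single arrays 1 to 2 lists were called, of which the chaperones remained each time and the ribosomal proteins without copper 2 or control 3, while the high light inducible list was newly called without control 2. The replicate block changed no call of a gene list.

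In the field every setting with all 4 arrays of agreed label, or with all 6, gave 0 calls by limma, with 41 to 239 genes at an unadjusted p under 0.05, the highest under the replicate block. The field numbers come as 2 pairs only, whose deviations had a correlation of 0.42. Single arrays left out gave 3 to 25 calls, and 0 to 5 lists. With treatment from the source names 1 list was called. The genes differing between field and culture numbered 24 by titles, 26 by source names, 31 with the replicate block, and 1 to 35 without single arrays. The field difference in detected sync_ probes was 5.40 points with the positive-and-significant mark in place of the well-above-background mark.

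Changes of sign were all in named genes that were not called, and the cause was not tested. In the culture, Syncc9902_0517 had 0.014 with normexp and 0.021 with the brightest probe, which gave 0.0019 for Syncc9902_1092. Without single arrays the ranges were -0.11 to 0.017 for Syncc9902_1092, -0.075 to 0.027 for Syncc9902_0517, -0.011 to 0.39 for Syncc9902_0916, -0.038 to 0.73 for Syncc9902_1814 and -0.092 to 0.72 for Syncc9902_0943. In the field, normexp gave 0.054 for Syncc9902_0916 and 0.047 for Syncc9902_0982, quantile normalization -0.013 for Syncc9902_1814, the brightest probe 0.021 for Syncc9902_0368, 0.0031 for Syncc9902_1949 and 0.043 for Syncc9902_0982, and the authors' values -0.026 for Syncc9902_1525. Treatment by titles gave -0.0088 for Syncc9902_0517, 0.42 for Syncc9902_1613, -0.060 for Syncc9902_1525 and 0.25 for sync_2264. Treatment by source names gave 0.31 for Syncc9902_2002, -0.061 for Syncc9902_1747, 0.0081 for Syncc9902_0824, 0.090 for Syncc9902_0368, 0.053 for Syncc9902_0916 and 0.059 for Syncc9902_0982. Without single field arrays the ranges were -0.32 to 0.10 for Syncc9902_1092, -0.27 to 0.23 for Syncc9902_2002, -0.055 to 0.24 for Syncc9902_1747, -0.47 to 0.18 for Syncc9902_0368, -0.40 to 0.30 for Syncc9902_0916, -0.47 to 0.16 for Syncc9902_1949, -0.30 to 0.22 for Syncc9902_0982, -0.83 to 0.35 for Syncc9902_1613 and -0.068 to 0.16 for Syncc9902_1525.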

Other observations

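The test of neighbouring locus tags in this part was chosen only after the result was seen.

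Several called genes lay outside the naming rule. A pseudouridine synthase (Syncc9902_2106), an RNA-modifying enzyme whose locus tag adjoins that of the LuxR-type regulator, rose by 2.75 ± 0.46 on the log2 scale (adjusted p = 0.0264). GTP cyclohydrolase I (Syncc9902_1631), the entry enzyme of folate synthesis, rose by 2.31 ± 0.37 (adjusted p = 0.0255), and the next tag, a short chain dehydrogenase (Syncc9902_1632), by 0.73 ± 0.14. A PhoH-like phosphate starvation-inducible protein (Syncc9902_1515) rose by 0.78 ± 0.14 (adjusted p = 0.0356) and its neighbour, the hypothetical protein Syncc9902_1514, by 1.43 ± 0.26. Syncc9902_0021, hypothetical and adjacent to DnaJ and Syncc9902_0020, rose by 2.64 ± 0.40. Among the lower genes, Syncc9902_2086, annotated as a low-complexity protein, fell by 1.08 ± 0.12 (adjusted p = 0.00673), and the hypothetical proteins Syncc9902_1457, Syncc9902_2041 and Syncc9902_2130 fell by 1.20, 0.88 and 0.81. Of the 15 called genes outside that rule, 0 stayed called without copper replicate 1 or control replicate 1, 2 without copper replicate 2, 1 without control replicate 3, 14 without control replicate 2 and 15 without copper replicate 3.

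Runs of adjacent tags led to a hypothesis that the called genes changed as groups of neighbours. Of the 41 called genes, 18 had a gene called in the same direction within 2 locus tags. Random draws of as many tested genes gave a median of 2 and a maximum of 10 over 10000 draws (permutation p = 1e-04, the smallest they can give). This is consistent with co-transcribed groups, a candidate explanation that the arrays do not test, because no transcript boundaries were measured. GrpE and DnaJ show that adjacent tags can also move apart.

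Spread differed between the genes called higher and those called lower. Both sets passed a test that weighs change against spread on these same arrays, so part of this difference may be built in. In the 24 called-higher genes the median SD over copper arrays was 0.83 and over control arrays 0.43, and in the 17 called-lower genes 0.21 and 0.23. With all genomes of the array tested in the culture, 1557 sync_ genes were above the filter and 0 were called by limma.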
